A study of Xenopus laevis and Mus musculus with 19 samples.

How the data were processed

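Growth cones and axons of retinal ganglion cells, the neurons that carry visual signals from the eye to the brain, were captured by laser microdissection, and their RNA was measured on Affymetrix arrays. The Xenopus laevis series held 14 arrays, with 5 of axons, 5 of growth cones from stage 24 embryos and 4 of growth cones from stage 32 embryos. The mouse series held 5 arrays of 1 group. Per the labels, whole eye primordia were cultured on membrane slides for 17 h at stage 24 and for 20 h at stage 32, and mouse retinal explants from embryonic day 15 were cultured for 24 h. RNA was extracted with the RNAqueous Micro kit, amplified with the 2-cycle TargetAmp kit and labelled with biotin.

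The deposited values were log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which did not state versions. The log base was not stated and was read from the range of the values and from the order of the spiked hybridization controls. The Xenopus and mouse tables were normalized separately, so that levels were never compared between species. No normalization was added in the main fits.

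The Xenopus array held 15611 probe sets. After removal of 120 control probe sets, 15491 were tested, of which 9304 carried 1 gene symbol, 195 several and 5992 none, for 7531 genes. The mouse array held 45101 probe sets, 64 of them controls, and of the 45037 others 34945 carried 1 symbol, 932 several and 9160 none. Symbols came from the platform annotation, and 9227 Xenopus probe sets were given their present symbol by Entrez gene identifier from the RefSeq annotation of assembly Xenopus_laevis_v10.1. The suffixes .L and .S name the homeologous copies of a gene on the long and short chromosomes of this allotetraploid species, and transcripts of both copies can bind to the same probes. Probe sets were not placed on the genome. Level differences were compared only within a probe set.

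Signal over background took the place of depth. On each array, the background level was the 95th percentile of probe sets for genes not expected in eye tissue. By that choice some probe sets of genes without expression exceed it, so that a single gene just above it need not be expressed. For Xenopus these were 44 probe sets of liver, pancreas and pituitary genes and the like, and for the mouse 143 probe sets of olfactory, vomeronasal and taste receptors, keratin-associated proteins and defensins. A probe set was above background in a group when its value exceeded that level on every array of the group. Where no array of a group reached background, the fold was given as a bound, with the mean background level of that group in place of its own mean. Such a bound holds for the group means only. It carries no sampling error, and the mean of the brighter group can include arrays under background. The number of arrays limits the precision of every value.

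Differences between the 3 Xenopus groups were tested with limma 3.58.1 in R 4.3.3. All 14 arrays entered a single linear model with 11 residual degrees of freedom, with moderated statistics and an intensity trend in the variance prior. The tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over the 15491 probe sets of a comparison, with a threshold of 0.05. Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, on 1 probe set per gene, the brightest over all arrays, and p-values were adjusted over 18 lists. The lists covered ribosomal proteins, the respiratory chain, translation factors, synaptic vesicles, actin regulators, microtubules and transport, axon guidance, the proteasome and ubiquitin, RNA-binding proteins, stress and immediate early genes, and transcripts known from axons of other studies. The other lists were markers of cells or cell bodies that a capture could take along, namely the cell cycle, eye transcription factors, glia, lens and epidermis, pigment epithelium, photoreceptors, and mesenchyme, muscle and blood. The fits and camera were tested on simulated data, with 200 of 15491 probe sets changed. At 2-fold, 75, 77 and 87 percent of changed probe sets were recovered for stage 32 against stage 24, stage 32 against axons and stage 24 against axons, with 7, 8 and 13 false calls. The simulated errors were independent between genes and arrays, and changes were planted only above the median level. These values therefore check the code and do not give the power or false call rate on the real arrays.

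Named genes followed a rule. For each Xenopus comparison, they were the 12 with the largest difference in each direction among probe sets with 1 symbol that passed and whose 2 groups did not overlap, and for each shifted list the 3 members with the smallest p. Where fewer than 5 passed in a direction, the 5 with the smallest p were taken and said not to pass. Mouse genes were up to 4 members per list with the largest margin over background, and the transcripts known from axons. The gene lists, the tests, the naming rule and most alternatives were set before the data were examined. Genes named outside the rule are said to be so.

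The mean of the ribosomal protein list and the mean of the hybridization controls were compared between groups with exact two-sided permutation tests, over 126 or 252 arrangements, adjusted over the 3 comparisons. Shares of list members above background, and the overlap of mouse and stage 32 Xenopus genes by symbol, were tested with Fisher's exact test, two-sided. Intervals at 95 percent were exact binomial. Single arrays far from the others of their group were found with Dixon's ratio. The Xenopus results were also counted over 100 splits of the arrays of both groups, drawn with a fixed seed and including the real split.

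Alternatives for the Xenopus results were quantile normalization, subtraction of each array's median, a fit of only the groups compared, a replicate block, array weights (statmod 1.5.0), a filter at the median level, no variance trend, adjusted p under 0.1, a minimum of 2-fold, 1 probe set per gene, the mean of a gene's probe sets and a correlation estimated per list. For the mouse they were the 90th and 99th percentiles, another background list, a requirement of 3 arrays and any probe set of a gene. Each replicate was left out in turn. Alternatives added after the data were examined left out 2 arrays, took the hybridization control level as a covariate, tested only probe sets above background, or set the Xenopus background by non-Xenopus control probe sets. The mouse arrays formed a single group, so that no difference between groups was tested there.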

Results

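RNA from the tips and the shafts of retinal axons was profiled in Xenopus laevis, and RNA from retinal axons growing out of explants was profiled in the mouse. The Xenopus arrays were in 3 groups, axons (n = 5), stage 24 growth cones (n = 5) and stage 32 growth cones (n = 4). The stage of the embryos behind the axon samples was not in the labels. The mouse arrays (n = 5) were growth cones by title and series design but axons by source name and description, and are called mouse samples here. The labels did not tie arrays to animals or cultures. The p-values therefore measured only the spread between these samples, which may have been technical, and they would be too small if captured regions shared animals. Signal was low on all arrays, with 581 to 1365 of 15491 Xenopus probe sets and 2860 to 4967 of 45037 mouse probe sets above background on an array. Correlations across probe sets, which are not independent replicates, ran from 0.747 to 0.969 within Xenopus groups and from 0.740 to 0.909 between them. Between mouse arrays they ran from 0.558 to 0.924.

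Ribosomal protein transcripts were the most widely detected of the 18 lists in each Xenopus group. Of 71 ribosomal protein genes, 52 were above background on all axon arrays (73.2 percent, against 3.37 percent of the other genes), 51 on all stage 24 growth cone arrays (71.8 percent, against 3.61 percent) and 35 on all stage 32 growth cone arrays (49.3 percent, against 2.32 percent). Fisher's exact test gave adjusted p = 2.7e-57, 4.1e-54 and 2.5e-35. Among them rps13.L, which codes for a protein of the small subunit, stood at 12.3 ± 1.51 (log2, mean ± SD) in axons, 12.2 ± 0.26 in stage 24 growth cones and 11.4 ± 1.32 in stage 32 growth cones. Of 7531 genes, 304 in axons, 319 in stage 24 growth cones and 208 in stage 32 growth cones were above background on every array.

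Of the 38 genes known from axons in other studies, 9 were above background on all axon arrays (23.7 percent, Fisher's exact test, adjusted p = 0.00013), 4 on all stage 24 arrays (adjusted p = 0.24) and 3 on all stage 32 arrays (adjusted p = 0.383). They included gap43.L, the growth-associated membrane protein, at 5.46 ± 0.55, 5.78 ± 1.0 and 5.37 ± 0.42 in axons, stage 24 and stage 32 growth cones. kpnb1.S, an importin that carries proteins to the nucleus, stood at 4.49 ± 0.13, 4.68 ± 0.21 and 4.56 ± 0.09. Actin regulators (7 of 52) and the respiratory chain (8 of 67) exceeded other genes in axons, each with adjusted p = 0.0234 by Fisher's exact test. The actin list and the list known from axons shared gap43.L, actb.L, cfl1.S and cfl1.L, so that their results overlap. Copies .L and .S counted as separate genes though they can bind to the same probes, and Fisher's test takes them as independent. In stage 24 and stage 32 growth cones the respiratory chain had 8 and 6 genes above background (adjusted p = 0.0648 and 0.0913), and the actin list 3 and 2 (adjusted p = 0.672 and 0.92). The guidance list had 4, 4 and 2 of 55 genes above background in axons, stage 24 and stage 32 growth cones and did not pass (adjusted p = 0.511, 0.597 and 0.92 by Fisher's exact test). The actin-sequestering thymosin tmsb4x.L was above background in each group, at 6.75 ± 0.88, 6.76 ± 0.40 and 6.78 ± 0.98. No gene of the cell cycle (51 genes), photoreceptor (15) or pigment epithelium (7) lists was above background on all arrays of any Xenopus group. Markers of other cells that were so in each group were glul.L (glutamine synthetase of glia), col1a1.S (collagen) and hbg2.L (globin), and in axons and stage 24 growth cones also the lens crystallins cryaa.S at 4.53 ± 0.10 and 4.59 ± 0.17 and cryba2.S at 4.52 ± 0.30 and 4.62 ± 0.36. Of the eye transcription factor genes, lhx2.L was above background on all arrays of each group, hes4.S in axons and stage 32 growth cones, and ebf2.L in the growth cones of both stages. In axons these were 1 of 11 glia, 2 of 32 mesenchyme, 2 of 28 lens and epidermis and 2 of 44 eye transcription factor genes. No marker list exceeded the other genes in any group (Fisher's exact test, smallest adjusted p = 0.383, for eye transcription factors at stage 32). These single genes therefore do not establish that other cells or cell bodies were captured.

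**Figure D1:**
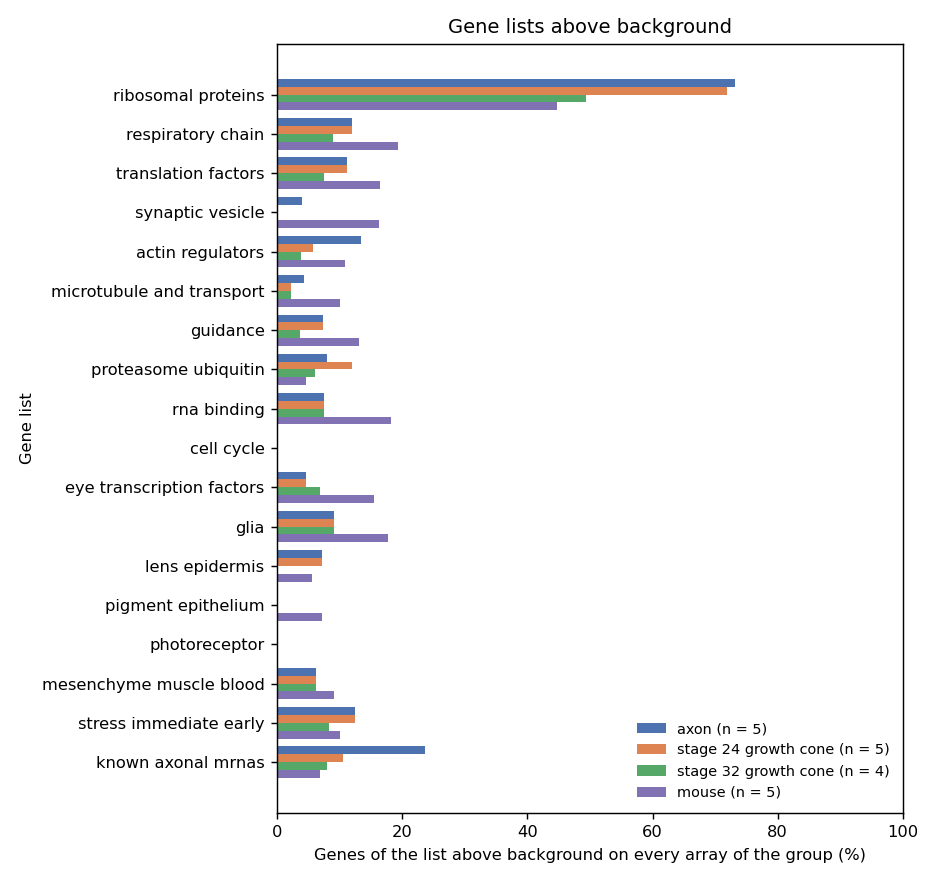
Share of the genes of each list that were above background on every array of a group, in percent, for the 3 Xenopus groups and the mouse samples. Ribosomal proteins reached 73.2 percent in axons, 71.8 percent in stage 24 growth cones, 49.3 percent in stage 32 growth cones and 44.7 percent in the mouse.

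Stage 24 growth cones were compared with axons to find transcripts whose level differed between the tip and the shaft. The 14-3-3 adaptor gene ywhab.S was at least 4.28-fold lower in growth cones, with 2.47 ± 0.23 (SD, n = 5) against 6.06 ± 1.36 (n = 5), above background on all axon arrays and on 0 growth cone arrays (adjusted p = 0.0118). The other 2 probe sets of ywhab.S differed by -0.13 and -0.08 and did not pass. The ribosomal stalk protein gene rplp2.L was 7.55-fold lower (5.71 ± 1.13 against 8.63 ± 1.28, adjusted p = 0.0457), with all arrays above background. The microtubule plus end protein gene mapre1.S was lower (3.48 ± 0.42 against 5.34 ± 0.51, adjusted p = 0.0408) and the cytochrome c oxidase gene cox7a2.S also (3.40 ± 0.67 against 6.33 ± 1.70, adjusted p = 0.048). Both were above background on all 5 axon arrays but on only 2 growth cone arrays, with a growth cone mean under background, so that no fold is given. Higher in growth cones was ppl.L, which codes for the desmosomal linker periplakin, by 2.42-fold (5.84 ± 0.44 against 4.57 ± 0.54, adjusted p = 0.0264), above background on 5 growth cone and 4 axon arrays. Its other probe sets differed by -0.11 and -0.05. Most of these calls were lost in most fits that left out a replicate, though no difference changed sign. In 10 fits with a replicate left out, that of ywhab.S was lost in 0, of rplp2.L in 9, of cox7a2.S in 8, and of mapre1.S and ppl.L in 7 each. With the hybridization control level as a covariate, chosen after the data were seen, 3 calls ended, with smaller differences and wider SEs. rplp2.L went from -2.92 (SE 0.728) to -2.14 (SE 0.918, adjusted p = 0.172), cox7a2.S from -2.93 (SE 0.740) to -2.24 (SE 0.95, adjusted p = 0.168) and mapre1.S from -1.86 (SE 0.444) to -1.44 (SE 0.568, adjusted p = 0.141). Growth cones here were those of stage 24, and not all differences held at stage 32. There mapre1.S (4.44 to 7.32) and ppl.L (4.69 to 5.03) overlapped the axon values (4.92 to 6.18 and 3.62 to 4.86). rplp2.L (4.72 to 7.84 against 6.76 to 10.19) and cox7a2.S (2.50 to 5.78 against 4.40 to 8.35) overlapped them in part. ywhab.S did not (2.47 to 3.20 against 4.32 to 7.84).

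Further genes met the naming rule with weaker signal. The tRNA synthetase gene eprs1.L was at least 1.67-fold higher in growth cones (4.82 ± 0.35 against 3.73 ± 0.45, adjusted p = 0.0237), above background on 5 growth cone and 0 axon arrays. The protease gene furin.L was at least 1.14-fold higher (4.27 ± 0.26 against 3.18 ± 0.24, above background on 4 and 0 arrays), tdrkh.L at least 1.33-fold (4.49 ± 0.61 against 3.28 ± 0.13, 3 and 0 arrays), purb.S at least 1.11-fold (4.23 ± 0.50 against 3.22 ± 0.34, 4 and 0 arrays) and rcc2.L at least 1.06-fold (4.17 ± 0.34 against 3.41 ± 0.27, 3 and 0 arrays). Lower in growth cones were the nucleolar chaperone gene npm1.L, at least 1.97-fold (2.44 ± 0.39 against 4.94 ± 1.56, above background on 0 and 3 arrays), and the beta-tubulin gene tubb.L, at least 1.26-fold (2.09 ± 0.09 against 4.29 ± 1.74, 0 and 2 arrays). The ATPase gene vcp.S was at least 1.37-fold lower (2.60 ± 0.39 against 4.41 ± 0.92, 0 and 2 arrays), taf8.S at least 1.17-fold (2.84 ± 0.35 against 4.19 ± 0.59, 0 and 2 arrays) and ahcy.S at least 1.20-fold (3.04 ± 0.28 against 4.22 ± 0.42, 0 and 3 arrays). The smallest bounds, such as 0.09 in log2 for rcc2.L and 0.15 for purb.S, did not exceed the SD of the background level between arrays. That SD was 0.15 in axons and 0.21 in stage 24 growth cones. Other probe sets of these genes did not pass, at 0.04 for tdrkh.L, 0.27 for eprs1.L, 0.28, 0.59 and 0.19 for furin.L, 0.48 for purb.S, 0.04 for tubb.L and -1.82 for npm1.L. At stage 32 the values of eprs1.L (3.84 to 4.09) and tdrkh.L (3.01 to 3.55) overlapped those of axons (2.95 to 4.06 and 3.05 to 3.37). Values of furin.L, rcc2.L, npm1.L and vcp.S also overlapped them in part, and those of purb.S, tubb.L, taf8.S and ahcy.S did not. No bound could be given for rrp1b.S and srrt.L (both higher, other probe set of srrt.L 0.20) or for ctnnb1.L (lower, other probe set 0.18). With a replicate left out, the calls of furin.L and ahcy.S were lost in 0 of 10 fits, of taf8.S in 1, of vcp.S in 2, of eprs1.L, tdrkh.L and purb.S in 5, of rcc2.L in 6, of npm1.L in 7 and of tubb.L in 9. Those of srrt.L, rrp1b.S and ctnnb1.L were lost in 6, 7 and 8. With the control level as a covariate 6 of the calls with a bound ended, all with a wider SE. The differences went from -1.18 (SE 0.202) to -0.91 (SE 0.244) for ahcy.S, -1.35 (SE 0.240) to -1.13 (SE 0.307) for taf8.S, -1.81 (SE 0.343) to -1.35 (SE 0.419) for vcp.S, -2.50 (SE 0.566) to -2.02 (SE 0.731) for npm1.L, -2.20 (SE 0.559) to -2.21 (SE 0.747) for tubb.L and 0.76 (SE 0.172) to 0.73 (SE 0.228) for rcc2.L. The calls of ctnnb1.L, from -1.04 (SE 0.266) to -0.75 (SE 0.336), and of bud31 also ended with the covariate (limma, adjusted p = 0.19 and 0.0824). Both groups were under background on every array for bud31, cwc22.S, ccdc3.L, sltm.S (all higher) and crygdl.30.L (lower).

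In all, 401 of 15491 probe sets passed limma's moderated test, 224 higher and 177 lower in growth cones, of which 230 carried 1 symbol. Only 38 of these were above background on all arrays of at least 1 group, 9 higher and 29 lower, among 694 such probe sets. The other 363 (215 higher, 148 lower) were not. The share called was 5.48 percent of the probe sets above background and 2.45 percent of the others. Since either group could place a probe set above background, a difference itself could raise the first share. The groups did not overlap at 1004 probe sets (6.48 percent), where chance gives 0.794 percent. Subtraction of each array's median turned the split to 175 higher and 224 lower, and quantile normalization gave 222 and 215. The count fell to 90 with the replicate block (31 higher, 59 lower) and to 147 with only the 2 groups fitted (61 higher, 86 lower), and rose to 1632 with array weights (976 higher, 656 lower). The count was 40 without axon replicate 2 or 3, 54 without axon replicate 4, 63 without axon replicate 1, 41, 199 and 247 without stage 24 replicates 5, 3 and 1, and 632 without stage 24 replicate 2.

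**Figure D2:**
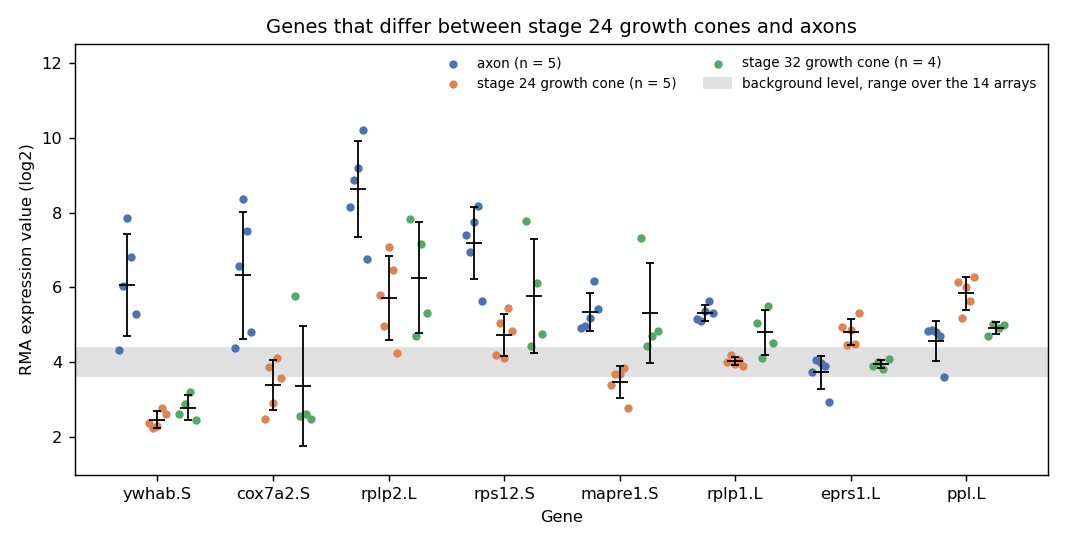
RMA expression value (log2) of 8 genes that differed between stage 24 growth cones and axons, with 1 point per array, bars for the mean ± SD of each group, and the range of the background level over the 14 Xenopus arrays in grey (3.64 to 4.38). ywhab.S stood at 6.06 ± 1.36 in axons and at 2.47 ± 0.23 in stage 24 growth cones, under background on each growth cone array.

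Ribosomal proteins were the only list of 18 that shifted between stage 24 growth cones and axons. Their median difference was -0.59 over 71 genes, 59 of them lower in growth cones (camera, adjusted p = 0.00058, but adjusted p = 0.911 with an estimated correlation). Lower were 3 members, rplp2.L, rps12.S (5.48-fold, 4.73 ± 0.57 against 7.19 ± 0.97, adjusted p = 0.0408, above background on 4 and 5 arrays) and rplp1.L (no fold given, since its growth cone mean lay at background, 4.03 ± 0.11 against 5.32 ± 0.21, adjusted p = 0.0185, above background on 2 and 5 arrays), and 68 did not pass. The call of rps12.S was lost in 7 of 10 fits with a replicate left out, and that of rplp1.L in 1. With the control level as a covariate the call of rps12.S also ended, from -2.45 (SE 0.584) to -1.67 (SE 0.712, adjusted p = 0.171). The count adjusted over the list alone was also 3. The mean of the list was 7.03 ± 1.14 on axon arrays and 6.32 ± 0.28 on growth cone arrays, a difference that did not pass (exact permutation test, p = 0.262, adjusted p = 0.393). The hybridization controls, spiked into every array, were higher on the growth cone arrays, at 10.04 ± 0.97 against 8.67 ± 0.50 (exact permutation test, p = 0.0238, adjusted p = 0.0357). The 3' control probe set of actin was lower on growth cone arrays (3.59 ± 1.01 against 6.05 ± 1.3) while its 5' probe set was not (3.89 ± 0.28 against 3.59 ± 0.42), and the 3' probe set of gapdh was higher (5.96 ± 1.12 against 4.29 ± 0.76). These differences were not tested. The call of the list ended with quantile normalization (median difference -0.20, adjusted p = 0.303) and without axon replicate 4 (-0.21, adjusted p = 0.337), and the median was -0.90 without axon replicate 5. Axon replicate 4 had the highest ribosomal protein mean of the axon arrays, 8.44. Its 3' probe set of the a3 actin gene also stood high, at 8.96 against 1.90 to 3.09 on the others. With the control level as a covariate the median difference turned to 0.48 (adjusted p = 0.477).

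Members of the other lists changed singly, and except for cox7a2.S and mapre1.S these changes stood at probe sets under background on every array of both groups or had no bound. The respiratory chain (67 genes) had 1 member higher, uqcrc2.L, and 1 lower, cox7a2.S. Translation factors (54) had 1 higher, eif4e3.S, and the cell cycle list (51) had 1 higher, the mitotic kinesin gene kif11.S. Microtubule and transport genes (47) had 1 higher, dpysl4.L, and 2 lower, mapre1.S and tubb4a.S. Among axon guidance genes (55), rgma.L and slit2.S were higher by 0.57 and 0.35, and the ephrin receptor genes ephb3.L and ephb3.S were lower, with differences of -0.56 and -0.36. The proteasome list (50) had 2 higher, psmd2.L and psma7.S, and 1 lower, psmb1.S. The pigment epithelium list (7) had 1 higher, pmel.S, the photoreceptor list (15) had 1 higher, opn1lw.L, and the stress list (24) had 1 lower, the mitochondrial chaperone gene hspd1.S. No member passed in the actin (52), synaptic vesicle (25), RNA-binding (27), eye transcription factor (44), glia (11), lens and epidermis (28) or mesenchyme, muscle and blood (32) lists, with the smallest adjusted p of a list other than ribosomal proteins at 0.312 for glia. Adjusted over the list alone, the counts were 3 higher and 4 lower for microtubules, 3 and 3 for guidance, 1 and 2 for photoreceptors and 1 and 0 for lens and epidermis. For the other lists they equalled those over all probe sets, except for transcripts known from axons. That list (38) had 0 members passing over all probe sets but 1 higher and 4 lower when adjusted over the list alone. Among the 4 were the actin gene actb.L (4.06 ± 0.33 against 6.33 ± 1.28, above background on 3 and 5 arrays, adjusted p = 0.0827 over all probe sets) and the actin-severing cofilin gene cfl1.L (4.06 ± 0.53 against 5.29 ± 0.55, 3 and 5 arrays, adjusted p = 0.0891). The median, the mean and the direction of camera differed in sign for the proteasome, RNA-binding, photoreceptor, mesenchyme and stress lists.

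Stage 32 growth cones were compared with the same 5 axon arrays, so that the comparisons with axons are not independent and no shared effect is read from them. Ribosomal proteins had a median difference of -1.25 over 71 genes (camera, adjusted p = 4.3e-13, but adjusted p = 0.987 with an estimated correlation). No member passed, over all probe sets or adjusted over the list alone. The members with the smallest p were rpl29.L (5.46 ± 1.36, n = 4, against 7.70 ± 1.33, n = 5, adjusted p = 0.354), rpl7.L (3.94 ± 2.03 against 6.61 ± 1.35, above background on 1 of 4 and 5 of 5 arrays, adjusted p = 0.354) and rplp2.L (6.26 ± 1.48 against 8.63 ± 1.28, adjusted p = 0.38). The mean of the list was 5.76 ± 1.85 on the growth cone arrays and 7.03 ± 1.14 on the axon arrays, a difference that did not pass (exact permutation test, p = 0.222, adjusted p = 0.393). Stage 32 replicate 1 stood at 8.39 and the other 3 at 4.35 to 5.69. The median difference moved with single growth cone arrays, to -2.21 without stage 32 replicate 1, -0.74 without replicate 2 and -0.82 without replicate 4, and the list passed in each case. The hybridization controls were higher on the growth cone arrays, at 10.1 ± 0.79 (exact permutation test, p = 0.0238, adjusted p = 0.0357), and with their level as a covariate the list did not pass (median difference -0.08).

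No single gene passed between stage 32 growth cones and axons in the main analysis. limma called 0 of 15491 probe sets, with 1374 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0796, at ywhab.S (2.80 ± 0.32, n = 4, against 6.06 ± 1.36, n = 5), which was above background on all axon arrays and on 0 growth cone arrays. Its other probe sets differed by 0.53 and -0.19. The detoxifying enzyme gene gstm1.S had 2.83 ± 0.51 against 6.02 ± 1.74 (adjusted p = 0.165, above background on 0 and 4 arrays). The next smallest p-values among genes lower in growth cones were at taf8.S (2.77 ± 0.18 against 4.19 ± 0.59), med10.S and larp1b.L, and among those higher at dhtkd1.L, bhmt.L, ssr4.S, thbs1.L and tpm1.L, which were under background on every array. Other probe sets differed by 0.24 for bhmt.L, -0.23 and 0.02 for ssr4.S, 0.07 for thbs1.L and -0.24 and -0.27 for larp1b.L. Adjusted over the list alone, 1 actin gene was lower (actg1.L, difference -1.17) and 1 higher (tpm1.L, 0.46), 1 pigment epithelium gene was lower (tyrp1.L, -0.71) and 1 higher (mitf.L, 0.42), and 1 gene each was lower in the mesenchyme list (col3a1.S, -0.68) and the stress list (hspd1.S, -0.54), none of them above background on all arrays of a group. The count of probe sets was 27 without axon replicate 5, 6 without stage 32 replicate 1 and 1 without axon replicate 1 or 3. It was far larger with array weights, 264, and without stage 32 replicate 1 and axon replicate 5 together, 178, a removal chosen after the data were seen. With quantile normalization 1 probe set passed, that of ywhab.S (adjusted p = 0.0044). The lists shifted were 4 without stage 32 replicate 1 (ribosomal proteins, respiratory chain, translation factors and genes known from axons), 3 without axon replicate 5 (ribosomal proteins, respiratory chain and glia) and 2 without axon replicate 1 (ribosomal proteins and glia). At the correlation estimated in the main fit every list had adjusted p = 0.987.

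**Figure D3:**
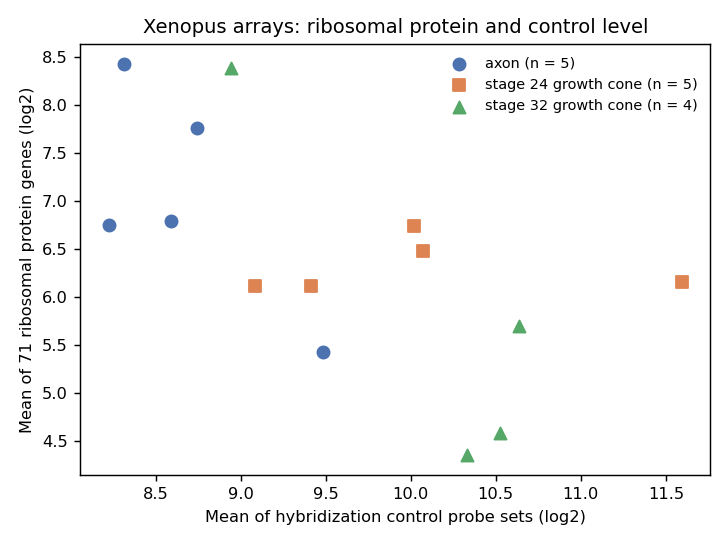
Mean RMA expression value (log2) of 71 ribosomal protein genes against the mean of the hybridization controls (log2), with 1 point per Xenopus array and a symbol for each group. Stage 32 replicate 1 had a ribosomal protein mean of 8.39 and a control mean of 8.94, and axon replicate 5 had 5.43 and 9.49.

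Growth cones of stage 32 and stage 24 were compared to ask whether the transcripts of the growth cone differ with age. A single probe set passed limma's moderated test, 1 of 15491, with 1774 at an unadjusted p under 0.05. It carries no gene symbol and stood at 2.70 ± 0.15 (n = 4) at stage 32 and 2.05 ± 0.13 (n = 5) at stage 24, under background on all arrays (difference 0.65, SE 0.092, adjusted p = 0.041). It is named outside the rule, after its value was seen. Its call was lost without stage 24 replicate 5 and without stage 32 replicate 1, 2 or 4, where 0 probe sets passed, and 3 or 4 passed without stage 24 replicate 1, 2, 3 or 4. Among genes with the smallest p, none passed and none was above background on all arrays of a group. Those with higher values at stage 32 were mitf.L, the melanocyte transcription factor (2.74 ± 0.20 against 2.16 ± 0.09, adjusted p = 0.0847), atic.L, pcbd1.L, tmem126a.L and tff3.8.S. Those with lower values were amotl1.L (2.31 ± 0.11 against 3.12 ± 0.21, adjusted p = 0.0776), cul3.S, the motor gene myh9.L, srrt.L (2.94 ± 0.22 against 4.02 ± 0.50, above background on 0 and 2 arrays) and mix23.S. Other probe sets differed by -0.12 for mitf.L, 0.22 for atic.L, -0.16 and 0.27 for pcbd1.L, 0.15 and 0.32 for tmem126a.L and 0.03 for srrt.L.

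No list shifted between the growth cone stages by camera (0 of 18, with 2 at an unadjusted p under 0.05), and the smallest adjusted p was 0.241. Ribosomal proteins had a median difference of -0.50, and the 25 synaptic vesicle genes 0.05. Over all probe sets 0 list members passed, and adjusted over the list alone 1 guidance gene was lower at stage 32, slit2.S (-0.34), and 1 pigment epithelium gene higher, mitf.L (0.58, other probe set -0.12). The hybridization controls differed by 0.07 between the stages, which did not pass (exact permutation test, p = 0.889). Without stage 32 replicate 1, 2 lists passed, ribosomal proteins (median difference -1.40) and the respiratory chain (-0.12). Ribosomal proteins also passed, lower at stage 32, with quantile normalization (-0.46, camera, adjusted p = 0.0061), the replicate block (-0.82, adjusted p = 0.0072), array weights (-1.05, adjusted p = 2.7e-05) and the filter at the median level (-0.56, adjusted p = 0.0157). All of these calls rest on the small correlation preset in camera. The correlation estimated for ribosomal proteins in the main fit was 0.686, which gave adjusted p = 0.969 between the stages, and it was not combined with these alternatives.

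The mouse samples were examined for the transcripts they held. Ribosomal proteins and the respiratory chain were above background more often than other genes. Of 47 ribosomal protein genes 21 were above background on all 5 arrays (44.7 percent against 7.21 percent, Fisher's exact test, odds ratio 10.4, adjusted p = 4.2e-11), and of 83 respiratory chain genes 16 were (19.3 percent against 7.25 percent, odds ratio 3.05, adjusted p = 0.0026). Members with the largest margin over background were Rps28 (11.1 ± 1.53, n = 5), Rps29 (10.2 ± 2.15), Rps20 (8.82 ± 2.43) and Rpsa (8.38 ± 2.54), and in the respiratory chain Cox6b1 (7.55 ± 3.65), Cox8a (5.06 ± 0.66), Atp5d (5.25 ± 2.23) and Cox6a2 (3.85 ± 0.04). Mouse genes were judged by their brightest probe set. Probe sets above background on all arrays were 3 of 3 for Rps28 and Rps29, 2 of 4 for Rps20 and 2 of 3 for Cox8a. They were 1 of 2 for Rpsa, Cox6b1, Atp5d and Cox6a2. In all, 1317 of 18026 genes were above background (7.31 percent). The ribosomal protein mean was 6.36 and 7.40 on replicates 4 and 5 and 2.95 to 3.42 on the other 3, whose hybridization controls stood at 11.9 to 12.47 against 8.41 and 9.0. The labels give no batch for these arrays.

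Genes of the cytoskeleton above background in the mouse included Tmsb10, a thymosin (10.3 ± 2.17), and the tubulin genes Tuba1a (8.34 ± 2.89) and Tubb2b (6.24 ± 1.93). The actin list (10.9 percent) and the microtubule list (10 percent) did not exceed the other genes (7.30 percent each, Fisher's exact test, adjusted p = 0.645 and 0.664). Dctn1, Kif1b, Limk1, Arpc4 and Cttn were also above background but differed by less than 1 log2 unit between arrays. Guidance genes included the semaphorin genes Sema3f (8.30 ± 1.19) and Sema6c (5.89 ± 1.17) and the hedgehog pathway gene Smo (6.76 ± 3.53), the last at 9.12 to 9.65 on replicates 1 to 3 but 2.74 and 3.05 on replicates 4 and 5. Sema3f (8.66, 9.14 and 9.40 against 7.83 and 6.46) and Sema6c (6.47, 6.73 and 6.67 against 5.61 and 3.96) were also higher on replicates 1 to 3, opposite to the ribosomal proteins. Only 1 of 3 probe sets of Sema3f, 2 of 3 of Sema6c and 1 of 3 of Smo were above background on all arrays. The shares were 2 of 5 for Tmsb10, 1 of 3 for Eif3h and Hspa5, 2 of 2 for Rab3a, and 1 of 1 for Tuba1a and Tubb2b. Synaptic vesicle genes included Rab3a (5.10 ± 0.12), and translation factors Eif3h (5.03 ± 1.36). Of 29 genes known from axons, 2 were above background on all 5 arrays, Tubb2b and the chaperone gene Hspa5 (4.02 ± 1.18), 12 on some arrays and 15 on none. Cfl1, Eef1a1, Stmn1, Cox4i1 and Ranbp1 were above on 4 arrays, Sod1 on 3, Actb and Prdx2 on 2, and Gap43, Vim, Atp5g1 and Stmn2 on 1.

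The other mouse lists did not pass in the main analysis against the remaining genes, although members were above background. Above background were 9 of 55 translation factors (adjusted p = 0.104 by Fisher's exact test, the smallest of these lists), 8 of 49 synaptic vesicle, 6 of 33 RNA-binding, 12 of 92 guidance, 6 of 39 eye transcription factor, 3 of 17 glia, 5 of 46 actin, 6 of 60 microtubule, 4 of 73 lens and epidermis, 3 of 30 stress, 3 of 33 mesenchyme, 2 of 43 proteasome and 1 of 14 pigment epithelium genes. The cell cycle (36) and photoreceptor (19) lists had 0. Under alternatives some passed by Fisher's exact test. Translation factors did so at the 90th percentile of background (adjusted p = 0.00497), with the other background list (0.00864), with 3 arrays required (0.0194) and without replicate 2 (0.0050) or 5 (0.0419). Synaptic vesicle genes did so under the first 4 of these (0.00497, 0.0141, 0.0312 and 0.0143), and microtubule genes without replicate 2 (20 percent, adjusted p = 0.0206). The member with the largest margin within each marker list was Epcam (5.05 ± 0.81, with 5.87, 5.66 and 5.38 on replicates 1 to 3 and 4.18 and 4.19 on replicates 4 and 5), Sparc (4.34 ± 0.18), Neurod2 (2.80 ± 0.01), Slc1a3 (2.42 ± 0.20) or Slc45a2 (2.48 ± 0.29). Only 1 probe set of each was above background on all arrays, of 2 for Epcam and Slc45a2, 3 for Sparc and Neurod2 and 6 for Slc1a3. Six3 held the value 2.35 on all 5 arrays. The count of 1317 genes was 140 at the 99th percentile of background and 2253 at the 90th, and 720 with the other background list.

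**Figure D4:**
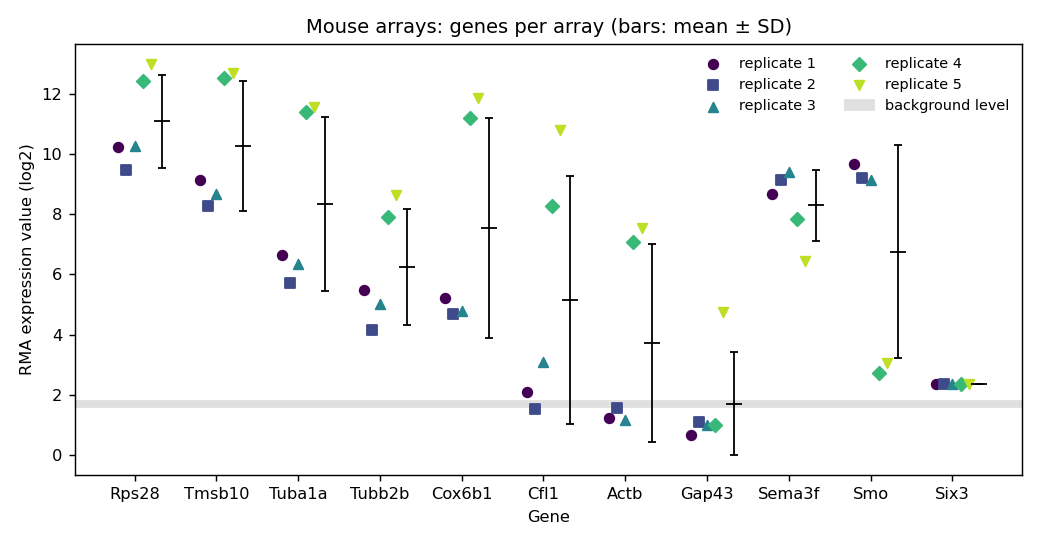
RMA expression value (log2) of 11 genes on the 5 mouse arrays, with 1 symbol per replicate, bars for mean ± SD, and the range of the background level in grey (1.60 to 1.78). Rps28 stood at 9.48 to 13.01, whereas Smo was at 9.12 to 9.65 on replicates 1 to 3 and at 2.74 and 3.05 on replicates 4 and 5.

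Genes above background in both species were counted by symbol, with the compartment of the mouse samples left open. Ribosomal proteins made up 13 of the 24 symbols above background in both the mouse samples and stage 32 Xenopus growth cones, among them Rps14, Rpl19 and Rplp2. The other 11 were Fau, which codes for a ribosomal protein outside the list, Ppl (periplakin), the nucleoside kinase gene Nme2, the phosphatase scaffold gene Ppp2r1a, and Aanat, Ahdc1, Bmp1, Micos10, Plod3, Rusc1 and Tmem259. Of 5288 symbols on both arrays, 454 were above background in the mouse and 147 in Xenopus, with 12.6 in both expected by chance (odds ratio 2.14, 95 percent interval 1.3 to 3.37, Fisher's exact test, p = 0.0023). Without the ribosomal protein list, a count made after the data were examined, 11 of 5251 symbols were shared where 10.4 were expected (odds ratio 1.06, Fisher's exact test, p = 0.869).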

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

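The tests of control probe sets at background, of the mouse values across arrays and of the control level as a covariate for the ribosomal proteins were chosen only after their results were seen. The comparison of the ribosomal means without a covariate, the test of calls above background and the splits of the arrays were set before.

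Single arrays stood far from the others of their group in 21 of 185 groups of 4 or 5 arrays, where chance flags about 1 in 20 groups and 9.25 would be expected. Most of them were stage 32 growth cone replicate 1 or axon replicate 5. On stage 32 replicate 1, the 3' probe set of gapdh (8.21, the others 3.62 to 4.26) and of actin (5.37, the others 2.57 to 2.81) stood high, and the median of the array stood low (2.43, the others 2.48). Its means were also high for the respiratory chain (4.07, the others 3.06 to 3.15), translation factors (4.03, the others 2.95 to 3.03), synaptic vesicle genes (3.37, the others 2.98), microtubule genes (3.31, the others 2.80) and RNA-binding proteins (3.003, the others 2.75 to 2.79). On axon replicate 5, low values were those of the 5' probe sets of gapdh (1.70, the others 1.92 to 1.98) and actin (2.86, the others 3.68 to 3.87), of the mesenchyme list (2.80, the others 2.96 to 3.01), and of ppl.L (3.62, the others 4.70 to 4.86), eprs1.L (2.95, the others 3.75 to 4.06), purb.S (2.63, the others 3.21 to 3.44) and tdrkh.L (3.05, the others 3.30 to 3.37). Its value for sltm.S was high (2.27, the others 2.05 to 2.11). Axon replicate 4 was high for the 3' probe set of the a3 actin gene (8.96, the others 1.90 to 3.09) and for RNA-binding proteins (3.04, the others 2.78 to 2.84), and low for srrt.L (2.82, the others 3.15 to 3.25). Stage 32 replicate 4 was high for the 5' probe set of gapdh (2.14, the others 1.91 to 1.93), and stage 32 replicate 3 for taf8.S (3.03, the others 2.64 to 2.71).

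The effects of the growth cone stages against axons differed at 1 probe set without a gene symbol by 0.65 (SE 0.092, adjusted p = 0.041), with 0.40 for stage 32 and -0.25 for stage 24. This difference is the comparison of stage 32 with stage 24 growth cones, since the axon arrays are shared.

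Ribosomal protein values were lower in growth cones than in axons by camera, with list means lower by -0.71 (SE 0.76) at stage 24 and by -1.28 (SE 0.80) at stage 32, though camera gave adjusted p = 0.911 and 0.987 with an estimated correlation. Since the hybridization controls are spiked in equal amounts, arrays with less sample signal may show higher controls after normalization, and the controls were higher on growth cone arrays. With the control level as a covariate, the difference at stage 24 was 0.42 (SE 0.88) and at stage 32 -0.09 (SE 0.93), with a slope of -0.83 (SE 0.41) per log2 unit of control. A technical difference in sample signal and a difference of the captured compartment cannot be told apart, because the control level differed between the groups and each of these intervals spans both 0 and the difference without the covariate. The stage of the axon samples, which the labels do not give, and the condition of the RNA, on which the 3' probe sets of actin and gapdh moved in opposite directions, were not tested and stay open too.

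Most calls between stage 24 growth cones and axons, 363 of 401, lay at probe sets not above background, as did most probe sets tested. The share called was 2.45 percent at these probe sets against 5.48 percent at those above background (Fisher's exact test, p = 1.3e-05). A probe set counted as above background through either of the groups compared, so that a difference itself favoured its entry. These shares therefore cannot decide where the calls concentrated. Of 50 control probe sets for sequences of other organisms, 34 percent (95 percent interval 21.2 to 48.8) had an unadjusted p under 0.05 in limma, against 19.8 percent of the Xenopus probe sets. The interval counts probe sets as independent, though several stand for the same sequence on the same arrays, and may be too narrow. A difference in non-specific signal between the arrays is a candidate explanation for the calls not above background. Of the 38 calls above background, 30 had a larger difference than any of the controls, whose largest was 0.88. These calls were selected for passing and for their level, and the controls were not. The comparison therefore cannot decide whether non-specific signal had a part there. Non-specific signal, the sample signal carried by the arrays and the captured compartment all stay open for those calls.

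Genes above background in the mouse outside the ribosomal proteins mostly had nearly constant values. Of 1296 such genes, 83.0 percent differed by less than 1 log2 unit between the lowest and the highest array, and 38 held an identical value on all arrays, whereas 0 of 21 ribosomal protein genes differed by less than 1 log2 unit (median range 5.11 against 0.48). Some values recurred at different genes, such as 2.35 on several arrays at Six3, Slc45a2, Elavl1 and Acta2, and 2.44 at Unc5a, Psmd4, Pcbp2 and Ddx6. Such values are not particular to a probe set, do not establish expression, and how they arise was not tested. Values that do not follow the sample are a candidate explanation for many of these genes, but less so for the respiratory chain (3 of 16 under 1 log2 unit, median range 3.70), the microtubule list (2 of 6, 2.85) and the 2 genes known from axons (0 of 2, 3.65). The mouse samples formed a single group, so that no biological explanation was tested.

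Chance was judged by 100 splits of the arrays. For stage 24 growth cones against axons, 1 split, the real one, gave as many as 401 probe sets, and the highest other gave 32. Chance was thus unlikely for that count if the arrays were independent, which the labels do not show. The count fell to 40 without axon replicate 2 or 3. The splits cannot tell the compartment from other differences between the arrays of the groups. Chance could not be excluded for 3 counts of 1, the probe set between growth cone stages (7 splits, highest other 12), the list for stage 32 growth cones against axons (76 splits, highest other 9) and the list for stage 24 growth cones against axons (61 splits, highest other 6). Where the real count was 0, every split gives at least as many by construction, and the 100 of 100 splits say nothing about chance. This holds for the lists between stages (highest other 4) and for the probe sets between stage 32 growth cones and axons. There a split called 177, which points to a structure of the samples other than the groups, and what it is was not tested.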

How the results depend on the processing

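The test on only the probe sets above background, the control level as a covariate, the removal of 2 arrays and the background set by control probe sets were chosen after seeing the data. Values are given for stage 32 against stage 24 growth cones, stage 32 growth cones against axons and stage 24 growth cones against axons, in that order, where 1, 0 and 401 probe sets and 0, 1 and 1 lists passed. Subtraction of each array's median gave 1, 0 and 399 probe sets and the same numbers of lists. With quantile normalization, 1 probe set passed for stage 32 against axons, and the lists became 1 between stages (ribosomal proteins, as in each single list added between stages below) and 0 for stage 24 against axons. Fits of only the groups compared, which have fewer arrays, gave 0 probe sets between stages and 147 for stage 24 against axons. Array weights gave 4, 264 and 1632 probe sets, 1 list between stages and 2 lists for stage 32 against axons. The filter at the median level gave 0 probe sets and 1 list between stages, and the fit without the variance trend 5 probe sets there. At adjusted p under 0.1, which by construction can only add calls, the counts were 14, 1 and 974. A minimum of 2-fold left 0 between stages and 57 for stage 24 against axons, and 1 probe set per gene, with fewer tested, left 0 and 177. With the correlation estimated per list, 0 lists passed in either comparison with axons. Without axon replicate 5 and stage 32 replicate 1 together, the probe sets were 75, 178 and 743 and the lists 2, 5 and 2. With the control level as a covariate, 0 probe sets passed between stages and 611 for stage 24 against axons, and 0 lists passed in either comparison with axons, with the median of the ribosomal proteins reversed to 0.48 at stage 24. Tested on probe sets above background only, the counts were 9, 1 and 85, over fewer tests. This filter admits a probe set through either group compared and so favours those that differ. The replicate block gave 0 and 90 probe sets for the comparisons between stages and of stage 24 with axons, and 1 and 2 lists between stages and for stage 32 with axons. The replicate numbers share only a number between groups. Arrays of the same number correlated at -0.17 to 0.012, -0.38 to 0.15 and -0.15 to 0.097, and 0, 0 and 1 arrays correlated best with their own number. Leaving out each replicate in turn gave 0 to 4, 0 to 27 and 40 to 632 probe sets and 0 to 2, 1 to 4 and 0 to 1 lists. The extremes of 27, 632 and 40 came without axon replicate 5, without stage 24 replicate 2, and without axon replicate 2 or 3, and the lists rose to 2 and 4 without stage 32 replicate 1 and dropped to 0 without axon replicate 4. For the mouse, the genes above background were 2253 at the 90th percentile, 140 at the 99th, 720 with the other background list and 2543 with 3 arrays required, and 1346 to 1597 with a replicate left out. The genes above background in both species were 68 at the 90th percentile, 7 at the 99th and 52 with 3 arrays required, 24 with the background set by control probe sets, and 24 to 30 with a replicate left out, with p from 5.1e-06 to 0.016 over the 15 alternatives. Except where the construction is named, the cause was not tested. Named genes kept their sign in all 930 cases, but of the 25 calls at named genes 21 were lost under at least 1 alternative, 20 of them when a replicate was left out, and 4 were never lost (furin.L, sltm.S, ywhab.S and crygdl.30.L). The direction camera gave a Xenopus list was kept in 921 cases and changed in 120. The side of a mouse list's share against that of the other genes was kept in 160 and changed in 20, and 10 results of lists passed there only under an alternative, 5 for translation factors, 4 for synaptic vesicle genes and 1 for microtubule genes. Signal over background limits all of these results.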

Other observations

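Probe sets above background that passed between stage 24 growth cones and axons also included genes outside the naming rule, chosen after their values were seen. Lower in growth cones was ptma.S, which codes for the chromatin-associated prothymosin (4.11 ± 0.43 against 5.26 ± 0.60, n = 5 each, adjusted p = 0.0435, above background on 4 and 5 arrays). Its growth cone mean lay near background, so that no fold is given. The glycolytic enolase gene eno1.S was lower by 1.96-fold (4.30 ± 0.30 against 5.27 ± 0.40, adjusted p = 0.0305, all arrays above). The protein-folding enzyme gene ppib.S was lower (3.61 ± 0.10 against 4.60 ± 0.50, adjusted p = 0.0237, above on 1 and 5 arrays) and the helicase gene ruvbl2.L also (3.87 ± 0.47 against 4.76 ± 0.25, adjusted p = 0.0473, above on 3 and 5 arrays). No fold is given for these, nor for bcas2.L below, since the lower mean was under background. Higher in growth cones were cyp51a1.L, of sterol synthesis, at least 1.40-fold (4.56 ± 0.21 against 3.89 ± 0.19, adjusted p = 0.0306, above on 5 and 0 arrays), and the splicing gene bcas2.L (5.11 ± 0.70 against 3.90 ± 0.50, adjusted p = 0.046, above on 5 and 2 arrays).

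Some receptors and ligands of axon guidance were above background on every array of a group, although the guidance list as a whole did not exceed the other genes. For single genes near that level this does not establish expression. The ephrin ligand gene efna3.L stood at 4.88 ± 0.28 in axons (n = 5), 5.50 ± 0.29 in stage 24 growth cones (n = 5) and 5.12 ± 0.12 in stage 32 growth cones (n = 4), and the difference between stage 24 growth cones and axons did not pass (0.62, adjusted p = 0.113 in limma). The receptor gene epha8.L stood at 5.20 ± 0.28 and 5.14 ± 0.29 in growth cones of stage 24 and stage 32, above background on all arrays of each, while a further probe set of the gene was not above background in any group. The ubiquitin-activating enzyme gene uba1.L, with 4.83 ± 0.20, 5.47 ± 0.57 and 4.57 ± 0.21, the chaperone gene hsp90ab1.S, with 5.10 ± 0.36, 4.94 ± 0.37 and 4.90 ± 0.24, and the translation elongation factor gene eef1d.S, with 5.67 ± 0.49, 5.34 ± 0.50 and 5.91 ± 0.56 in axons, stage 24 and stage 32 growth cones, were above background in all 3 groups. The eye transcription factor gene lhx2.L was so at 1 of its probe sets, with 4.17 ± 0.19, 4.57 ± 0.30 and 4.48 ± 0.17.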
